A study of Arabidopsis thaliana with 12 samples.

How the data were processed

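The series measured RNA from whole Arabidopsis seedlings of 3 genotypes, with or without flg22 for 30 min, in 12 libraries that form 6 groups of 2. Per the series' design text there were independent repeats of the experiment, and each library combines the RNA of 2 biological replicates, so the spread between the libraries of a group is a spread between pools. The dose of flg22 is 100 nM in the series' design text and 100 mM in the labels' treatment protocol, a disagreement that stays open here. Libraries were made with an Illumina TruSeq kit per the labels' protocols and read as single ends of 100 nt per the design text; neither states whether the reads keep their strand, so antisense and overlapping genes cannot be told apart.

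The deposited values are FPKM per the file headers, a unit of fragments scaled to transcript length and library size. How the library size was set is not stated in the headers. The submitters' processing notes name bcl2fastq 1.8.4, cutadapt 1.0, TopHat2 2.0.12, Cuffdiff 2.2.1 and the build TAIR10, without their roles. A table of all samples and a file per sample hold the same values, the latter rounded to 4 decimals. No counts or library totals are given, so confidence intervals from counts are not possible. FPKM is already divided by library size and transcript length, and column sums ran from 981.2 to 1249.4 when divided by 1000. MT1A, a metallothionein gene, took 1.46 to 1.78% of the sum in libraries of repeat 1 and 10.17 to 16.07% in those of repeat 2. As a stand-in for depth, the FPKM of a single read was read off the lowest nonzero values of genes with transcripts of 2.5 to 8 kb, which puts the scale at 6900000 to 8200000 reads in repeat 1 and 6000000 to 11600000 in repeat 2. This scale is an estimate, sought within fixed limits, and entered no test.

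The table has 33373 lines with a gene identifier and 693 without, which were left out. So were 88 identifiers listed more than once (176 lines, 18 of them at the level of the filter), and 33197 identifiers stayed. Of these 32732 were matched by locus tag to names in the RefSeq annotation of TAIR10.1, used for names, gene classes and transcript lengths; positions in the text are from that annotation and not from the authors' files. Genes with near-identical copies are uncertain, since how multiply mapped reads were treated is not given in the sources used here.

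Genes with at least 1 FPKM in at least 2 of the 12 libraries were kept (20753). On log2(FPKM + 1) a linear model with a mean for each of the 6 groups was fitted in R 4.3.3 with limma 3.58.1, with a mean-variance trend and robust empirical Bayes moderation. P values of genes were adjusted by the Benjamini-Hochberg method within each comparison, and a gene passed at an adjusted p under 0.05. All p values are 2-sided. The plan named a count model for the case that counts were deposited, and limma on log2 values for normalized units such as FPKM, which applied. The comparisons were flg22 against none in each genotype, each line against WT in each condition, and the difference of the flg22 response of each line from that of WT. Comparisons that share a group also share its chance values.

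Named genes followed a rule. ASR3 is always named. In the response of WT the 10 largest rises and falls are named, and in every other comparison the 5 largest, among genes past the test with a mean of at least 1 FPKM over all libraries and, except for differences of response, with both libraries of one group above both of the other. From a gene list, up to 4 members with the smallest adjusted p in the comparison are named, with ties ordered by unadjusted p. In flg22 responses and their differences FRK1, WRKY29, WRKY33, WRKY53, NHL10, CYP81F2, PHI-1 and MYB51 may be named as well. The same rule was applied to the models with a block after the data were seen.

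The 17 gene lists hold 369 genes, of which 349 names appear in the reference annotation. They cover early flg22 markers, WRKY factors, immune receptors, the MAP kinase cascade, salicylic acid, jasmonate, ethylene and ERF factors, indole glucosinolate and camalexin synthesis, calmodulin-like proteins, auxin, abscisic acid and cold, heat shock, low oxygen, the circadian clock, photosynthesis, root markers and trihelix factors. The photosynthesis and root lists serve as markers of tissue, and some genes stand in more than 1 list. Lists were tested with camera at a preset correlation of 0.01, with an estimated correlation beside it, adjusted over the 17 lists of a comparison. The self-contained test fry was also run. Counts adjusted over the list alone use the same gene p values, adjusted within the list.

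For flg22-raised genes, the list came first from the genotype that was not compared: OX9 against WT used genes raised at least 2-fold with adjusted p under 0.05 in asr3-1, and asr3-1 against WT those of OX9. Lists chosen in WT itself and lists with no fold minimum were also set beforehand, and lists from the model with the replicate block were added after the data were seen. Since the list from OX9 was empty, genes at least 2-fold higher within each of the 2 repeats of the third genotype, with no test, were added after the data were seen. For each kind of list and setting, p values were adjusted together over both lines, the 3 comparisons of each, and raised and lowered genes. Correlations of the differences of both lines from WT were set against 100 simulated draws of unchanged groups.

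Replicate numbers were checked for pairing before the models were compared. The deviations of repeat 2 from repeat 1 correlated across genes in each of the 15 pairs of groups, at 0.57 to 0.81, so libraries with the same number moved together. The first 2 principal components held 48.6% and 28.1% of the variance. Both separate the repeats within each treatment, and the treatment within each repeat. Within a group the 2 libraries correlated at 0.891 to 0.921. The model with the replicate number as a block therefore stands beside the model without it where it changes a call or a count. A further model with blocks for the repeat and for the repeat's own response to flg22 (repeat-by-treatment block) was added after the repeats were seen to differ in their response; its spread leaves out how far the flg22 response differs between repeats.

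The code was tested on simulated data in the layout of the comparison of flg22 in WT, 20753 genes with 50 changed at each size. Without the block it recovered 14% of genes raised by 1 on the log2 scale, 64% of those raised by 2, 72% of those raised by 3 and 4% of those lowered by 1, with 2 false calls. With the block the shares were 64, 96, 98 and 74%, with 13 false calls, and with the repeat-by-treatment block 72, 96, 98 and 70%, with 8. The simulated genes had the same response in both repeats, and their noise came from the model with the repeat-by-treatment block. These shares thus leave out how far the response differs between repeats, and large changes could be missed too. In WT, CYP81F2 at log2 5.70 did not pass in limma even with the replicate block (adjusted p = 0.093).

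Alternatives planned beforehand were the replicate block, the groups of a comparison alone, each library left out in turn, a minimum of 2-fold, quantile normalization, trimmed mean scaling, no filter except a value above 0 in 1 library, a pseudocount of 0.1, no mean-variance trend, and for lists an estimated correlation, fry, the block and both scalings. Added later were the repeat-by-treatment block, genes with transcripts of at least 1000 bases, the lists of genes raised in both repeats, and differences averaged over conditions. A model of counts was not run, as the values are FPKM. Tables were prepared and figures drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.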

Results

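Transcript levels were measured by RNA sequencing in whole Arabidopsis seedlings, Col-0 background, at 10 days of age. The plants were of 3 genotypes: wild type (WT), the mutant asr3-1, and OX9, a line that carries ASR3 with an HA tag behind the 35S promoter, a strong promoter active in most plant tissues. ASR3 (AT2G33550) is a transcription factor of the trihelix family. Seedlings of each genotype were either left without flg22, a peptide of bacterial flagellin that the receptor FLS2 perceives, or given flg22 for 30 min. The 6 groups had 2 libraries each, from independent repeats of the experiment, 12 libraries in all. Values are FPKM, so the number of reads is not given directly. The lowest nonzero FPKM values of genes with transcripts of 2.5 to 8 kb put the scale of each library between 6000000 and 11600000 reads. In a library 19148 to 19635 genes reached 1 FPKM. Group levels below are means of 2 libraries unless a library or a repeat is named. Differences were tested with limma on log2(FPKM + 1) over 20753 genes unless another test is named.

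ASR3 itself was read first, since it checks the genotype labels. Its gene lies on the minus strand of chromosome 2 at 14209982 to 14211693 (TAIR10.1) and has 3 exons. In OX9 the transcript stood at 556 ± 48.8 FPKM (SD, n = 2) without flg22 and at 484 ± 142 FPKM with it, against 7.91 ± 2.37 and 7.44 ± 1.55 FPKM in WT. These were rises of 5.99 and 5.83 on the log2 scale, with adjusted p = 0.0055 and 0.0068. The mutant held 4.54 ± 2.88 FPKM without flg22 and 2.99 ± 0.646 FPKM with it, log2 differences from WT of -0.76 and -1.08 that did not pass the test (adjusted p = 1 for both). Within each repeat and each condition the asr3-1 library was below its WT counterpart, while the asr3-1 library without flg22 of repeat 1, at 6.58 FPKM, lay above the WT libraries of repeat 2, at 6.24 and 6.34 FPKM. Reads of this gene were thus still present in the mutant, and a loss of the transcript is not shown here. Treatment with flg22 left ASR3 within its error in WT (log2 -0.07, SE 0.39), in asr3-1 (-0.38) and in OX9 (-0.23), with an adjusted p of 1 in each.

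**Figure D1:**
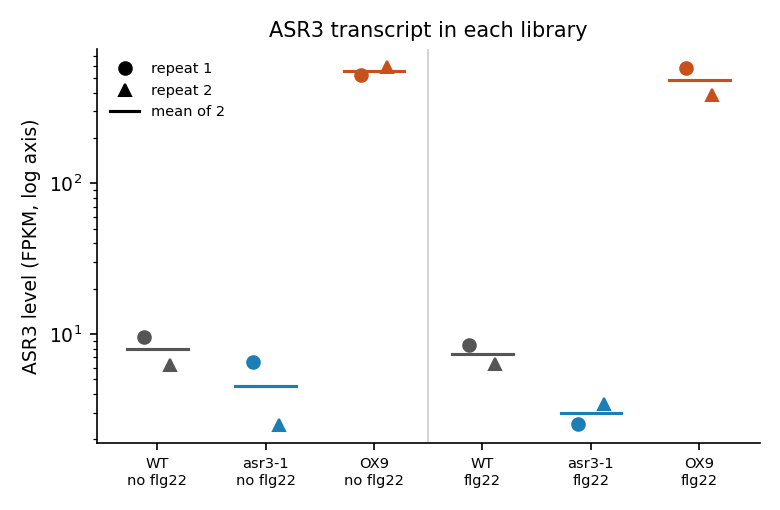
ASR3 level in each of the 12 libraries, in FPKM on a log axis, with circles for repeat 1, triangles for repeat 2 and a line at the mean of 2. OX9 libraries lie between 384 and 590 FPKM, WT libraries between 6.24 and 9.59 and asr3-1 libraries between 2.5 and 6.58.

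The first question was which genes flg22 changes in WT. After 30 min, 21 genes were higher and none lower past the test, among 1407 genes at an unadjusted p under 0.05. The largest rise was in AT1G71520, from 0.359 ± 0.147 to 119 ± 86.3 FPKM (log2 6.25, SE 0.79, adjusted p = 0.045). Next came the pseudogene AT4G23215 (log2 5.02), AT3G15518 (4.39), AT4G21920 (4.28), the peroxidase family gene AT1G14550 (4.07), AT1G49000 (4.0), the chitinase family gene AT2G43620 (3.96), the receptor-like kinase AT1G51820 (3.57), MLO12, a relative of the mildew susceptibility protein MLO (3.51), and the chitinase EP3 (AT3G54420, 3.38), with adjusted p between 0.024 and 0.045. MLO12 went from 10.3 ± 2.67 to 139 ± 82.9 FPKM. With the replicate number as a block, 108 genes were higher and 9 lower, all 21 of the first count among them. The genes added by the block include the zinc finger gene ZAT11 (log2 6.24), the peroxidase PER4 (5.63) and the ethylene response factor ERF105 (5.23) on the higher side. On the lower side they include MIR834 (log2 -1.37), LGO, a cell cycle inhibitor (log2 -0.76, 63.5 ± 0.532 to 37.1 ± 2.46 FPKM, adjusted p = 0.027 with the block), and the co-chaperone BAG2 (-0.80, 0.042). MIR834 went from 69.7 to 25.4 FPKM in WT. In asr3-1 it went from 56.7 to 66.7 and in OX9 from 67.6 to 62.3, so no such fall was seen in these lines.

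The lists of genes fixed beforehand place this response in known immune pathways. Of the 24 measured early flg22 markers, 23 were above 0, with a median log2 of 3.28. Of them 3 passed the test over all genes (MLO12, the elicitor peptide precursor PROPEP2 at 2.24 and the ubiquitin ligase PUB22 at 2.97), and 21 passed adjusted over the list alone. The receptor kinase FRK1, a classic flg22 marker, gave 3.02, and the indole glucosinolate enzyme CYP81F2 5.70, neither past the test. Both passed in limma with the repeat-by-treatment block (adjusted p = 0.03 and 1.3e-06). That block was added after the data were seen, and its spread leaves out how far the response differs between repeats. With the replicate block, WRKY29 (2.33, adjusted p = 0.027) and NHL10 (1.65, adjusted p = 0.038) passed as well. As a group the markers were raised by camera (adjusted p = 3.4e-34), a call lost with an estimated correlation (adjusted p = 0.067 with an estimated correlation).

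All 20 genes of ethylene synthesis and ERF factors were above 0 (median 1.93, adjusted p = 1.6e-16), none past the test singly and 11 adjusted over the list alone. This was the list whose call also held with an estimated correlation (adjusted p = 0.029), though not once the replicate block was added (adjusted p = 0.10 with both). Receptors and receptor-proximal signalling genes were above 0 in 31 of 31 members, median 1.81, with 1 past the test and 6 adjusted over the list alone. They include the flg22 receptor FLS2 (1.18), the receptor kinase LORE (1.82) and the ubiquitin ligase PUB23 (3.85), and the list had adjusted p = 3.3e-22 (adjusted p = 0.14 with an estimated correlation). MAP kinase cascade genes were above 0 in 17 of 17 (median 1.5, adjusted p = 1.3e-11), with 0 past the test and 2 adjusted over the list alone (adjusted p = 0.15 with an estimated correlation). Examples are the kinases MKK9 at 1.48 and MKK4 at 2.73. Among 37 WRKY factors 30 were above 0 (median 0.83, adjusted p = 6e-14), with 0 and 12 passing (adjusted p = 0.083 with an estimated correlation). Calmodulin-like calcium sensors were above 0 in 12 of 13 (median 1.69, adjusted p = 6.6e-11), with 0 and 6 passing (adjusted p = 0.098 with an estimated correlation).

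Indole glucosinolate and camalexin genes were above 0 in 18 of 21 (median 0.72, adjusted p = 6.3e-08), with 0 and 3 passing, and adjusted p = 0.14 with an estimated correlation. IGMT2, which methylates indole glucosinolates, stood at 5.85 and the myrosinase PEN2 at 2.57. Salicylic acid genes were above 0 in 17 of 20 (median 0.70, adjusted p = 1.6e-06, no member past the test either way, adjusted p = 0.15 with an estimated correlation), with the regulator SARD1 at 3.82 and WRKY70 at 2.33. Jasmonate genes were above 0 in 21 of 29 (median 0.22, adjusted p = 0.0098, no member past the test either way, adjusted p = 0.25 with an estimated correlation), with the lipoxygenase LOX4 at 5.90 and the repressor JAZ1 at 1.98.

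Beyond defence, heat shock genes were above 0 in 15 of 15 (median 0.97, adjusted p = 1.8e-05), with 0 and 2 passing and adjusted p = 0.25 with an estimated correlation. Their median was 1.45 in repeat 1 and 0.38 in repeat 2, the opposite order to the immune lists, whose early markers gave 2.46 and 4.25. Low-oxygen genes were above 0 in 15 of 15 (median 0.60, adjusted p = 6.1e-06), with 0 and 2 passing and adjusted p = 0.083 with an estimated correlation; with the replicate block the estimated correlation gave an adjusted p of 0.041. The transcription factor LBD41 (1.99) and WIP4 (1.91) lay highest among them. Photosynthesis genes, the markers of green tissue, lay below 0 in all but 2 of 26 members by a small amount (median -0.15, adjusted p = 0.0018, no member past the test either way, adjusted p = 0.36 with an estimated correlation), and after quantile normalization that call was lost (median -0.07, adjusted p = 0.67). The lists of auxin response (adjusted p = 0.79), abscisic acid and cold response (0.79), circadian clock (0.77), root markers (0.51) and trihelix factors (0.79) did not pass. The count of genes for WT was 0 without either WT library lacking flg22 and 0 without the treated library of repeat 2, and 22 without the treated library of repeat 1. With no filter on level it was 3, and with the 4 WT libraries alone 0.

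**Figure D2:**
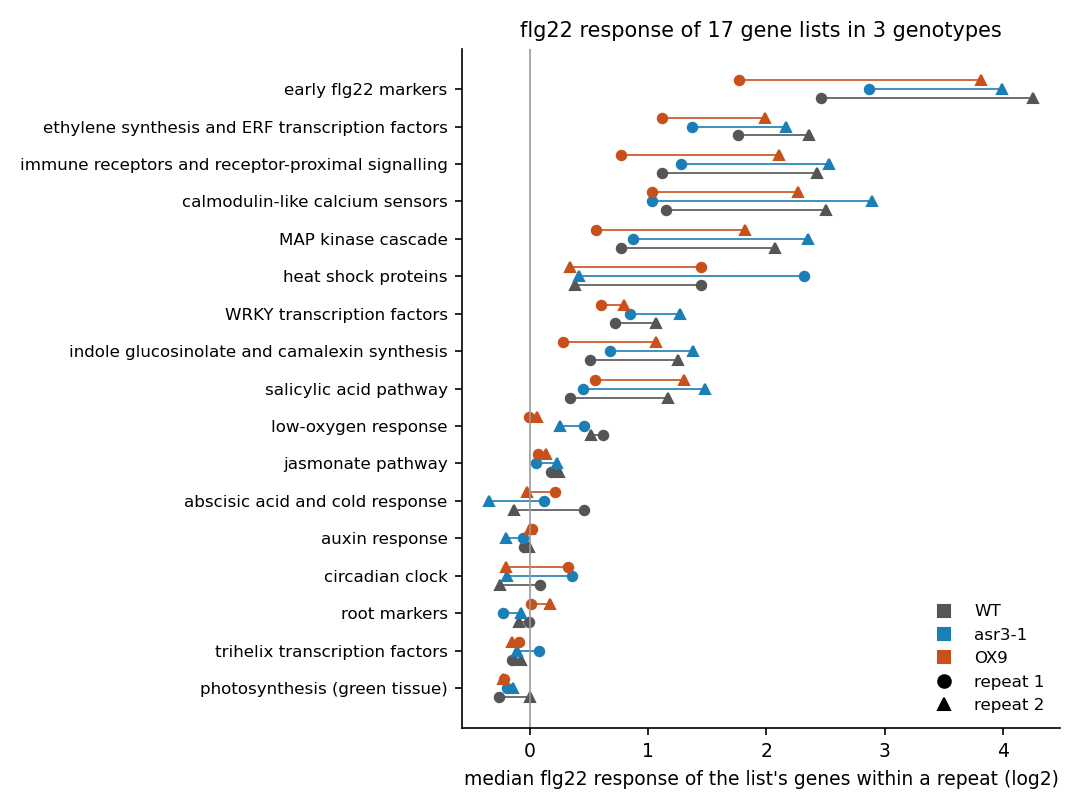
Median log2 response to flg22 of the genes of each of 17 lists, within repeat 1 (circles) and repeat 2 (triangles), in WT (grey), asr3-1 (blue) and OX9 (orange). Early flg22 markers give the highest medians, from 1.77 to 4.25, and the low-oxygen list lies at 0.62 and 0.52 in WT but at -0.01 and 0.06 in OX9.

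In the mutant, flg22 raised 40 genes and lowered none past the test (1631 genes at an unadjusted p under 0.05). AT5G05300 went from 0 to 255 ± 238 FPKM, AT1G71520 from 0 to 146 ± 137 and AT1G51920 from 0 to 55.7 ± 3.64, so no fold is given for these. The peroxidase PER4 went from 3.95 ± 1.60 to 391 ± 303 FPKM (log2 6.09, SE 0.84, adjusted p = 0.044) and AT4G23215 from 2.25 ± 1.22 to 101 ± 47.2 (4.95, SE 0.60, 0.029). Among the early markers WRKY29, a factor long used as a readout of MAP kinase signalling, rose by 2.64 (adjusted p = 0.038). With the replicate block WRKY33 (4.18, adjusted p = 0.046) and NHL10 (1.76, adjusted p = 0.022) passed too. Of the 12 lists called in WT, 11 were called here in the same direction, while the jasmonate list was not (median 0.14, adjusted p = 0.075). With an estimated correlation 1 of the 11 calls held, and 0 with the replicate block added to it. Early markers were above 0 in 23 of 24 (median 3.33, adjusted p = 1.9e-32; 5 past the test, 21 adjusted over the list alone; adjusted p = 0.075 with an estimated correlation). Receptors followed with 30 of 31 (median 1.83, adjusted p = 2.1e-22; 2 and 12; adjusted p = 0.15 with an estimated correlation). Ethylene and ERF genes were above 0 in 20 of 20 (median 1.83, 0 and 10), and this call held with an estimated correlation (adjusted p = 0.041) but not with the replicate block added to it (adjusted p = 0.11). Heat shock genes gave a median of 1.43, with 2.32 in repeat 1 and 0.42 in repeat 2 (adjusted p = 3e-07; adjusted p = 0.17 with an estimated correlation). Photosynthesis genes lay above 0 in 1 of 26 (median -0.19, adjusted p = 9e-04; adjusted p = 0.36 with an estimated correlation; after quantile normalization -0.12, adjusted p = 0.12). Quantile normalization moves the median of all genes from -0.04 to -0.15 here, and from -0.01 to -0.13 in WT. With the block 330 genes were higher and 46 lower, and they include all 40. The count fell to 0 without any 1 of the 4 asr3-1 libraries and with these 4 libraries alone.

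In OX9 no gene passed the test after flg22 (limma, 949 genes at an unadjusted p under 0.05, smallest adjusted p = 0.0741). By camera 9 of the lists raised in WT were raised here too, without the jasmonate list (16 of 29 above 0, median 0.04, adjusted p = 0.23) and the low-oxygen list. With an estimated correlation 1 of the 9 calls held, and 0 with the replicate block added to it. Early markers lay above 0 in 23 of 24 members (median 2.68, adjusted p = 3.5e-30), with 0 past the test and 18 adjusted over the list alone (adjusted p = 0.089 with an estimated correlation). Receptors and receptor-proximal genes were above 0 in 29 of 31 (median 1.39, adjusted p = 1.1e-19, 0 and 6, adjusted p = 0.19 with an estimated correlation), and ethylene and ERF genes in 18 of 20 (median 1.49, adjusted p = 6e-14, 0 and 9), the latter also with an estimated correlation (adjusted p = 0.045), though not with the replicate block added to it (adjusted p = 0.19). In low-oxygen genes 8 of 15 members lay above 0, with a median of 0.05 (adjusted p = 0.88). Photosynthesis genes were below 0 in 26 of 26 (median -0.24, adjusted p = 3e-06; adjusted p = 0.21 with an estimated correlation; after quantile normalization -0.09, adjusted p = 0.41). The replicate block gave 10 genes, all higher, among them AT1G71520 (log2 5.86), AT1G14550 (3.31) and AT2G18323, which was listed at 0 without flg22. The count was 3 without the untreated OX9 library of repeat 1 and 0 without any of the other 3 OX9 libraries.

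The responses of the 3 genotypes share no library, but libraries of the same repeat moved together, which the overlap of independent lists leaves out. WT and asr3-1 shared 20 of their 21 and 40 raised genes, where independent lists would share 0.0405. No gene was called in all 3, as OX9 had none. With the replicate block WT and asr3-1 shared 101 raised genes (independent lists 1.72) and 9 were raised in all 3. The log2 responses correlated across genes at 0.86 for WT and asr3-1, 0.81 for WT and OX9 and 0.78 for asr3-1 and OX9, and genes are not independent replicates. Taken from repeat 1 of one genotype and repeat 2 of another, so that no repeat is shared, the correlations were 0.62 and 0.59 for WT and asr3-1, 0.58 and 0.49 for WT and OX9 and 0.53 and 0.49 for asr3-1 and OX9, a check added after the data were seen.

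Without flg22, no gene passed the test between asr3-1 and WT in limma (81 at an unadjusted p under 0.05), with or without the block, and 1 passed with no filter on level. On data simulated for flg22 in WT, also 2 libraries against 2, the model without a block found 14% of 2-fold rises and 4% of 2-fold falls. With the replicate block it found 64% and 74%. Changes of that size could thus have been missed, in that simulation less often with the block. Jasmonate genes lay slightly higher in the mutant, in 22 of 29 members with a median of 0.22 (adjusted p = 0.02, no member past the test over all genes or adjusted over the list alone). Examples are the repressor JAZ7 (1.31), the jasmonate-responsive TAT3 (1.56), the allene oxide cyclase AOC1 (0.49) and the allene oxide synthase AOS (0.33). Root markers lay lower in 13 of 18, with 5 above 0 and a median of -0.12 (adjusted p = 0.02). Both calls were lost with an estimated correlation (adjusted p = 0.80 and adjusted p = 0.46 with an estimated correlation) and with the replicate block (adjusted p = 0.076 for both). All medians of the other 15 lists lay between -0.08 and 0.22.

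OX9 without flg22 differed from WT in ASR3 and in AT2G01422, a noncoding RNA listed at 0 in WT and at 63.2 ± 30.2 FPKM in OX9 (adjusted p = 0.039). These were the 2 genes past the test, both higher (173 at an unadjusted p under 0.05). Auxin response genes lay lower, with 5 of 28 above 0 and a median of -0.17 (adjusted p = 0.0016, no member past the test over all genes or adjusted over the list alone, adjusted p = 0.078 with an estimated correlation). The repressors IAA29 (-0.79), IAA20 (-0.59) and IAA19 (-0.52) lay lower and LBD29 (0.71) higher. Early flg22 markers lay slightly higher before any treatment, in 16 of 24 members with a median of 0.27 (adjusted p = 0.033, no member past the test, adjusted p = 0.86 with an estimated correlation, adjusted p = 0.19 with the replicate block). Examples are PROPEP3 at 2.1, WRKY29 at 0.87, MLO12 at 0.83 and, on the other side, AT1G26390 at -0.70. WRKY factors lay higher in 28 of 37 (median 0.11, adjusted p = 0.033, no member past the test, adjusted p = 0.86 with an estimated correlation, 0.053 with the block). The trihelix list was called (adjusted p = 0.012; 0.14 with the block; adjusted p = 0.13 with an estimated correlation) through ASR3 itself, as its median was 0.03. The count of genes was 0 without either WT library or without the OX9 library of repeat 2, and 3 without the OX9 library of repeat 1. It was 1 with no filter, with a pseudocount of 0.1 or with long transcripts alone, and 0 with the 4 libraries of the contrast alone.

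With flg22, several immune lists lay a little higher in asr3-1 than in WT, while no single gene passed the test (limma, 166 at an unadjusted p under 0.05, 0 with the block). Early markers were above 0 in 19 of 24 (median 0.23, adjusted p = 0.00093), with AT1G26410 at 1.12, MLO12 at 0.79 and WRKY29 at 0.68. Indole glucosinolate and camalexin genes were above 0 in 19 of 21 (median 0.21, adjusted p = 0.00093), with the camalexin enzyme CYP71A12 at 1.23 and the glucosinolate enzyme CYP83B1 at 0.56. Receptors and receptor-proximal genes followed in 25 of 31 (median 0.15, adjusted p = 0.0025), with the kinases IOS1, LORE and PBL1 at 0.90, 0.58 and 0.52, and WRKY factors in 27 of 37 (median 0.15, adjusted p = 0.033, 0.065 with the block). Lower in the mutant were the low-oxygen list (1 of 15 above 0, median -0.35, adjusted p = 0.00019), with the oxygen-sensing enzyme PCO1 at -0.96 and SAD6 at -0.79, the root markers (3 of 18 above 0, median -0.21, adjusted p = 0.0018) and the auxin list (10 of 28 above 0, median -0.09, adjusted p = 0.045, 0.095 with the block). No member of these lists passed the test over all genes or adjusted over the list alone. With an estimated correlation none of the 7 calls held: adjusted p = 0.68 for the raised lists and adjusted p = 0.21 for the lowered lists with an estimated correlation. The count of genes was 1 without the treated WT library of repeat 1, and 1 with no filter.

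With flg22, 6 of 17 lists lay lower in OX9 than in WT, 3 of them of immunity and its hormones. Early flg22 markers were above WT in 1 of 24 members (median -0.54, adjusted p = 5.5e-05; adjusted p = 0.58 with an estimated correlation), with PROPEP3 at -1.16, PROPEP2 at -0.73 and MLO12 at -0.56. The low-oxygen list fell furthest, with 2 of 15 above 0 and a median of -0.60 (adjusted p = 1.5e-09; adjusted p = 0.077 with an estimated correlation; adjusted p = 0.021 with an estimated correlation and the block). WIP4 (-1.83), LBD41 (-1.64), PCO1 (-1.09) and the transcription factor HRA1 (-0.80) are examples, and 2 members passed adjusted over the list alone, none over all genes. Ethylene and ERF genes (3 of 20 above 0, median -0.44, adjusted p = 0.015; adjusted p = 0.41 with an estimated correlation) and jasmonate genes (7 of 29, median -0.17, adjusted p = 0.012; adjusted p = 0.41 with an estimated correlation) lay lower too, without a member past the test either way. So did the auxin list (7 of 28, median -0.12, adjusted p = 0.016; adjusted p = 0.18 with an estimated correlation). Photosynthesis genes lay lower in all but 3 of 26 (median -0.09, adjusted p = 0.015; adjusted p = 0.65 with an estimated correlation), a direction that flips after quantile normalization (median 0.03, adjusted p = 0.81). The lists of WRKY factors (adjusted p = 0.15), receptors (0.12), MAP kinases (0.12), salicylic acid (0.89), indole glucosinolates (0.67) and calmodulin-like sensors (0.068) did not pass.

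ASR3 was the 1 gene past the test in that comparison, with or without the replicate block (164 genes at an unadjusted p under 0.05). A block for repeat and for the repeat's own response to flg22, chosen after the data were seen, gave 4 higher and 4 lower. Besides ASR3 the higher ones were PAP22, a purple acid phosphatase (1.09 ± 0.483 FPKM in WT, 19.5 ± 4.59 in OX9), AT3G57160 (log2 1.46) and the pseudogene AT2G18323, listed at 0 in WT and at 7.15 ± 3.73 FPKM in OX9. The lower ones were WIP4 (12.4 ± 2.81 in WT, 2.75 ± 0.300 in OX9), AT1G58150 (log2 -1.58) and MIR848 (8.80 ± 5.67 FPKM in WT, listed at 0 in OX9), with another lower gene left unnamed because its OX9 libraries overlap those of WT, and adjusted p of the named genes lay between 0.023 and 0.047. AT2G18323 and MIR848 are not particular to OX9: with flg22, asr3-1 held 5.44 ± 1.19 FPKM of the former and 0 of the latter. For both, treated WT stood apart from both lines. Without that block the count was 2 without the treated WT library of repeat 1, 3 without the treated OX9 library of repeat 1, and 0 without either treated library of repeat 2 or with the 4 libraries of the contrast alone.

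The next question was whether the response to flg22 itself differs in the asr3-1 line, in which ASR3 reads were still present. The difference of the 2 responses, asr3-1 against WT, gave 0 genes in limma (80 at an unadjusted p under 0.05, 0 with the block) and 0 of 17 lists. Early flg22 markers had a median difference of 0.10, with 14 of 24 above 0 (adjusted p = 0.52), receptors and receptor-proximal genes 0.00 with 16 of 31 (0.49), and the low-oxygen list -0.25 with 2 of 15 (0.35). Single markers went both ways, such as FRK1 at 0.42 (SE 1.28) and WRKY33 at -0.37. The error of these single differences is large, so the values do not show that the responses were alike.

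For OX9 the same question was asked of the line with raised ASR3. In the difference of the responses, OX9 against WT, no gene passed the test in limma (95 at an unadjusted p under 0.05, 0 with the block), but 5 of 17 lists were lower and none higher. Early flg22 markers had a median difference of -0.73 with 2 of 24 above 0 (adjusted p = 2.5e-07, and 0.73 with an estimated correlation). Examples are PROPEP3 (-3.26), MLO12 (-1.38), CYP81F2 (-1.17, SE 1.71) and WRKY33 (-1.11, SE 1.65). Other markers differed less, such as WRKY53 at -0.57 and NHL10 at -0.24. The error of these single differences is large here too. For PROPEP3 and MLO12 much of the difference lay in a higher level without flg22. OX9 differed from WT by 2.1 and 0.83 without flg22, and by -1.16 and -0.56 with it. PROPEP3 was low in untreated WT, at 1.46 and 0.262 FPKM. Untreated means of CYP81F2 (7.07 against 3.55 FPKM) and WRKY33 (28.3 against 19.1) were higher in OX9 too. The low-oxygen list had -0.53 with 0 of 15 above 0 (adjusted p = 3.7e-08; adjusted p = 0.11 with an estimated correlation; adjusted p = 0.022 with an estimated correlation and the block). Ethylene and ERF genes had -0.49 with 2 of 20 above 0 (adjusted p = 0.011; adjusted p = 0.73 with an estimated correlation), with ERF1A at -0.77 and the ethylene synthesis gene ACS7 at -0.57. WRKY factors had -0.37 with 8 of 37 above 0 (adjusted p = 0.0037; adjusted p = 0.73 with an estimated correlation), and receptors -0.35 with 2 of 31 above 0 (adjusted p = 0.011; adjusted p = 0.83 with an estimated correlation). No member of these 5 lists passed over all genes or adjusted over the list alone. The replicate block added the photosynthesis list (median -0.09, adjusted p = 0.018; adjusted p = 0.78 with an estimated correlation and the block).

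LBD41 shows the low-oxygen case library by library. In WT it went from 10.6 and 6.84 FPKM to 28.4 and 47.8 with flg22, in asr3-1 from 9.19 and 6.69 to 19.7 and 38.2, and in OX9 from 11.1 and 6.98 to 11.7 and 10.7. WIP4 went from 3.32 and 1.91 FPKM to 10.4 and 14.4 in WT, from 2.57 and 0.759 to 8.62 and 9.54 in asr3-1, and from 3.34 and 1.44 to 2.96 and 2.54 in OX9. The difference of response did not pass the test for either gene (adjusted p = 1).

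**Figure D3:**
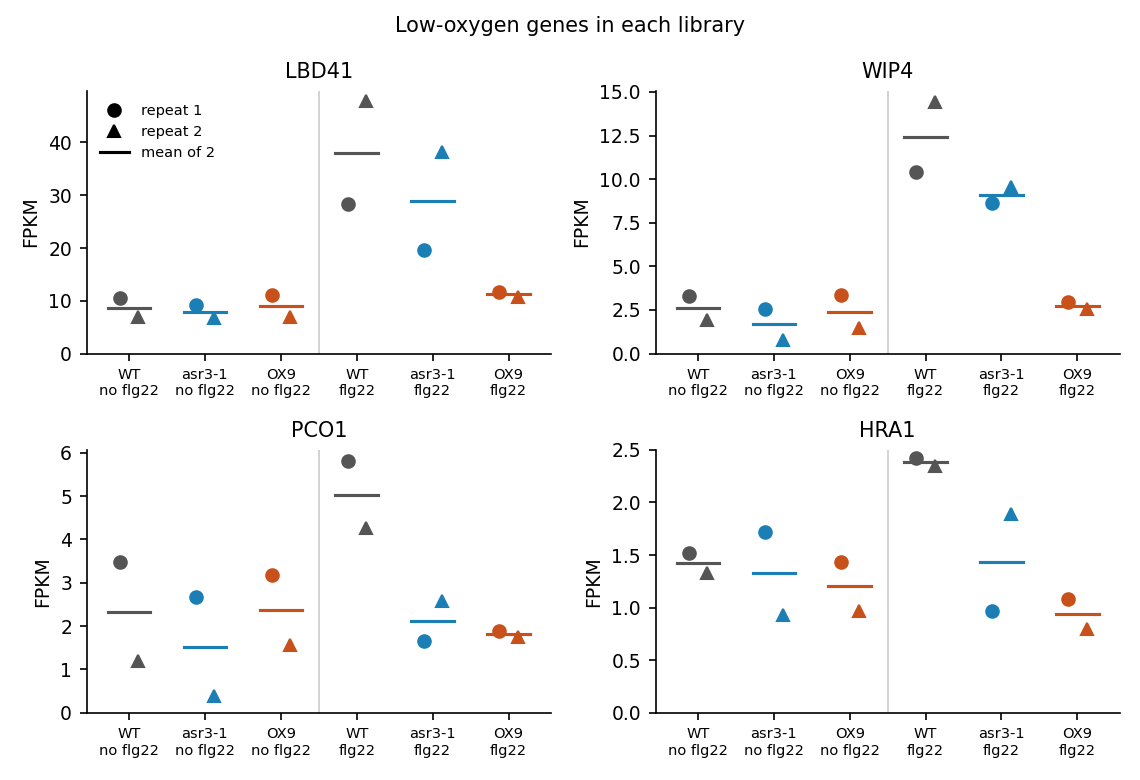
Levels of 4 low-oxygen genes in each library, in FPKM, with circles for repeat 1, triangles for repeat 2 and a line at the mean of 2. In WT, LBD41 reaches 28.4 and 47.8 FPKM with flg22, while the OX9 libraries with flg22 lie at 11.7 and 10.7.

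To look at flg22-raised genes as a whole, OX9 and WT were compared over genes raised in asr3-1, not chosen by their response in WT or OX9. The test behind the first list took its spread from all 12 libraries, so genes whose WT and OX9 repeats agreed passed more easily. Agreement between repeats over that list is thus partly a result of the choice. The 40 genes past the test in asr3-1, which include PER4, MLO12, PUB22 and the chitinase EP3, were already higher in OX9 than in WT without flg22 (median 0.39, 36 of 40 above 0, adjusted p = 2.9e-17; adjusted p = 0.081 with an estimated correlation). That difference was 0.76 in repeat 1 and 0.18 in repeat 2, and 0.11 without the untreated OX9 library of repeat 1. With flg22 they were lower (median -0.33, 1 of 40 above 0, adjusted p = 1.7e-09; adjusted p = 0.14 with an estimated correlation). Their difference of response was -0.77, lower in both repeats for 37 of 40 (adjusted p = 6e-28; adjusted p = 0.062 with an estimated correlation, which became 0.037 after quantile normalization, 0.046 after trimmed mean scaling and 0.25 with the replicate block). Within repeats the level with flg22 differed from WT by 0.01 in repeat 1 and -0.71 in repeat 2, and the difference of response was -0.73 and -0.89. Without the treated WT library of repeat 2 the level with flg22 stood at 0.05 (adjusted p = 0.38).

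A wider list held the 795 genes at least 2-fold higher with flg22 in both repeats of asr3-1, and it was set up after the data were seen. Its median response was 1.72 and 3.18 in repeats 1 and 2 of WT, 1.78 and 3.33 in asr3-1, and 1.18 and 2.69 in OX9. OX9 lay 0.14 above WT without flg22 (547 of 795 above 0, adjusted p = 0.0022; adjusted p = 0.85 with an estimated correlation) and 0.36 below it with flg22 (median -0.36, 79 above 0, adjusted p = 4.4e-11; adjusted p = 0.70 with an estimated correlation). The difference of response was -0.49, with -0.53 in repeat 1 and -0.45 in repeat 2, and 601 of the 795 genes lower in both (adjusted p = 9.5e-15; adjusted p = 0.67 with an estimated correlation). Leaving out 1 treated library sets 1 repeat against the other, and the median with flg22 then ran from -1.16 without the WT library of repeat 1 to 0.39 without that of repeat 2, with -1.08 and 0.35 for the OX9 libraries of repeats 2 and 1. The median difference of response ran from -1.30 to 0.26 over the same WT libraries, with -1.20 and 0.18 for the OX9 libraries. Untreated libraries moved a call too: the difference without flg22 did not pass without the WT library of repeat 2 (0.15, adjusted p = 0.082) or the OX9 library of repeat 1 (0.05, 0.69).

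For asr3-1 against WT the list was to be the genes raised in OX9, of which none passed the test. Planned beside it were the genes raised in WT itself, where chance can lift the response of WT. Over these 21 genes asr3-1 lay higher by 0.22 without flg22 (adjusted p = 2e-04; adjusted p = 0.28 with an estimated correlation) and by 0.39 with it (adjusted p = 4.2e-08; adjusted p = 0.15 with an estimated correlation), with a difference of response of 0.09 (adjusted p = 0.083). Over 10 genes raised in OX9 with the replicate block, a list added after the data were seen, the values were 0.13 (adjusted p = 0.071), 0.13 (9.4e-05; adjusted p = 0.093 with an estimated correlation) and 0.02 (0.022; adjusted p = 0.18 with an estimated correlation). Then the 487 genes at least 2-fold higher in both repeats of OX9 were used. Their median difference was 0.12 without flg22 (344 of 487 above 0, adjusted p = 0.21), 0.17 with it (370 above 0, adjusted p = 2.4e-05; adjusted p = 0.82 with an estimated correlation) and 0.06 for the difference of response (278 above 0, 0.01 in repeat 1 and 0.12 in repeat 2, adjusted p = 0.014; adjusted p = 0.85 with an estimated correlation). Here too, leaving out 1 treated library turned the direction: the median with flg22 was -0.72 without the WT library of repeat 1 and -0.79 without the asr3-1 library of repeat 2, and the difference of response -0.81 and -0.84. That difference also lost its call without the WT library lacking flg22 of repeat 2 (0.04, adjusted p = 0.097) or that of asr3-1 (0.05, 0.45).

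**Figure D4:**
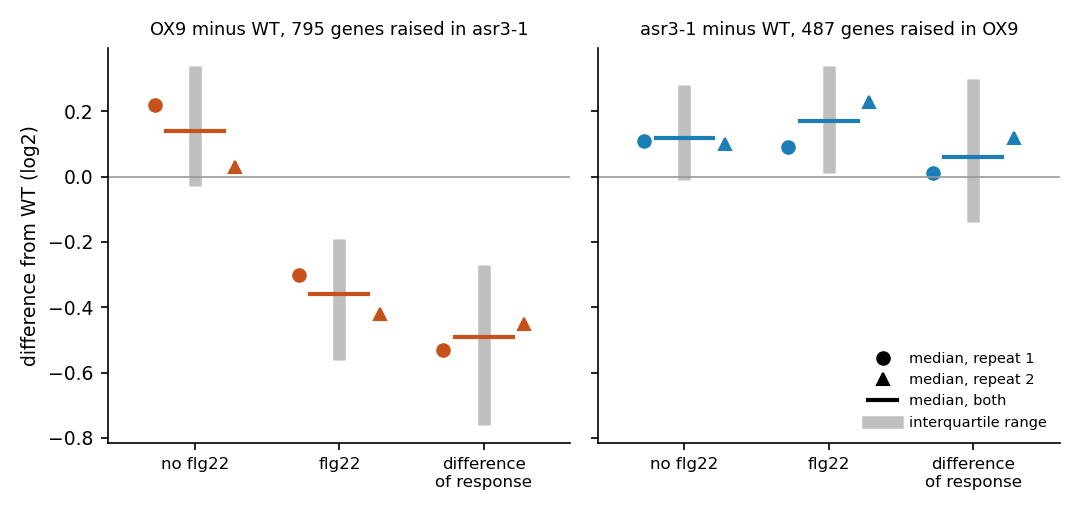
Median log2 difference from WT over flg22-raised genes, in OX9 over 795 genes raised in asr3-1 (left) and in asr3-1 over 487 genes raised in OX9 (right), with the interquartile range over genes in grey and the medians of repeats 1 and 2 as circles and triangles. The difference of response lies at -0.53 and -0.45 in OX9 and at 0.01 and 0.12 in asr3-1.

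The differences of asr3-1 and of OX9 from WT rest on the same WT libraries, which alone makes them correlate. Without flg22 they correlated at 0.42 across genes, where 100 simulations of unchanged groups gave a mean of 0.50 (0.42 to 0.55), and their covariance was 0.0392 against a simulated 0.0436. With flg22 the correlation was 0.34 (simulated mean 0.50, 0.42 to 0.58) and the covariance 0.0318 against 0.0436. The draws took genes as independent and their spread as equal in all groups, while in the real libraries genes moved together. A value outside the simulated range thus does not show a departure from unchanged groups. No gene was called in both. With asr3-1 taken from one repeat and OX9 from the other, so that no WT library is shared, the correlations were 0.05 and 0.00 without flg22 and -0.09 and 0.00 with it, against 0.33 to 0.48 within a repeat. Between its own 2 repeats each line's difference correlated at 0.02 to 0.09, so this check, added after the data were seen, could hardly have shown a shared effect.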

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

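All tests of explanations here were chosen after the results were seen, and so were the lists of genes moved in both repeats of the third genotype.

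In the difference of the flg22 response, OX9 against WT, camera called 5 of the lists chosen before the data were examined lower than the other genes. Their medians were -0.73 for early flg22 markers, -0.37 for WRKY factors, -0.35 for immune receptors, -0.49 for ethylene and ERF genes and -0.53 for low-oxygen genes. The self-contained test fry called 0 of the 17 lists in this comparison. Over genes raised in asr3-1 the median was -0.77 for 40 genes and -0.49 for 795, calls lost with an estimated correlation (adjusted p = 0.062 and 0.67), and the latter turned to 0.26 without the treated WT library of repeat 2 and to 0.18 without the treated OX9 library of repeat 1. Several technical explanations are argued against over the 795 genes: after trimmed mean or quantile scaling the median stayed at -0.41 or lower, it was -0.45 in the repeat closer to 0, and a misplaced WT is not enough, since OX9 responded less than asr3-1 too (-0.54 over 775 genes raised in WT, in the repeat closer to 0). For the low-oxygen list a misplaced WT was not tested, and asr3-1 also lay below WT there. Its median responses in repeats 1 and 2 were 0.62 and 0.52 in WT, 0.46 and 0.26 in asr3-1, and -0.01 and 0.06 in OX9. Over the 795 genes OX9 was also below WT with flg22, at -0.30 in the repeat closer to 0. A higher starting level in OX9 alone would not give that. The level with flg22 lost its call with an estimated correlation, so a higher starting level as the whole cause is not excluded. For the 40 genes that level was 0.01 in repeat 1. There a raised level without flg22 cannot be told apart from a smaller response. For the 5 lists a higher starting level was not tested within repeats. A smaller response in plants with high ASR3 may thus be a candidate explanation, while effects of the insertion or of how plants of this 1 line were handled stay open, and the 5 list calls were lost with an estimated correlation (adjusted p of 0.11 to 0.83) unless a block was added: low-oxygen genes then held with the replicate block (0.022), and they and ethylene and ERF genes with the repeat-by-treatment block (0.042 each).

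The repeats differ by transcript length. Repeat 2 minus repeat 1 rose with the length of the longest transcript in each of the 6 groups, with Spearman's rho across genes from 0.35 to 0.43, and the medians ran from between -0.31 and -0.24 for transcripts under 500 bases to between 0.26 and 0.36 for the class of the longest. Another sign is that 29 genes held at least 10 FPKM in all libraries of repeat 1 and 0 in all of repeat 2, with 0 genes the other way, and 23 of them have transcripts under 300 bases. No explanation of this trend was tested, so its source stays open. Both repeats hold every group, so the part of this trend that the groups share adds spread to the comparisons. Whether the trend differs between groups was not tested: rho was 0.35 in asr3-1 with flg22 and 0.43 in WT without it.

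The response to flg22 was larger in repeat 2 for immune lists and smaller for heat shock genes. Early markers in WT had medians of 2.46 and 4.25, against 1.45 and 0.38 for heat shock genes. Short transcripts did not make this difference in WT. Its median was 1.53 over the 775 raised genes and 1.57 over the 622 of them with transcripts of at least 1000 bases. Length itself is not excluded, since the trend with length went on above 1000 bases. Scaling alone is argued against by heat shock medians lower in repeat 2 by at least 0.85 in all 3 genotypes (-0.85 in the closest). A difference in the treatment or the plants between the repeats may remain, and no value here tests it.

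Small differences of response were also called for genes raised in both repeats of OX9 in asr3-1 against WT (median 0.06 over 487 genes, adjusted p = 0.014; adjusted p = 0.85 with an estimated correlation). Over 27 genes lowered in both repeats of OX9 the same comparison gave 0.08 (adjusted p = 0.046; 0.11 with the replicate block; adjusted p = 0.67 with an estimated correlation). Over 14 genes lowered in both repeats of asr3-1, OX9 against WT gave 0.07 (adjusted p = 0.031; 0.071 with the replicate block; adjusted p = 0.30 with an estimated correlation), with -0.28 in repeat 1 and 0.51 in repeat 2. Both lists of lowered genes were picked with no test and were lowered less elsewhere. The median response of the 27 genes was -1.41 in OX9, -0.15 in WT and 0 in asr3-1. For the 14 genes it was -1.34 in asr3-1, -0.68 in WT and -0.23 in OX9.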

How the results depend on the processing

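Counts of genes depend strongly on how the 2 repeats are modelled. In WT the 21 genes raised by flg22 became 117 changed genes with the replicate block and 2339 with the repeat-by-treatment block, the latter added after the data were seen. They became 3 with no filter and 0 with the 4 WT libraries alone, and leaving out 1 library gave 0 to 22. In asr3-1 the 40 genes became 376 and 2709 with these blocks, and 0 with its own libraries alone or with any 1 left out. In OX9 the count of 0 became 10 and 1883, and 0 to 3 with 1 library left out. Raised genes shared by WT and asr3-1 went from 20 to 101 with the replicate block, 1685 with the repeat-by-treatment block and 3 with no filter. Those shared by all 3 genotypes went from 0 to 9 and 1345 with these blocks.

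For asr3-1 against WT without flg22 the count was 1 with no filter and 0 with any library left out. OX9 against WT without flg22 gave 1 gene with no filter, a pseudocount of 0.1, the repeat-by-treatment block or transcripts of at least 1000 bases, 0 with its own groups alone, and 0 to 3 with 1 library left out. With flg22, asr3-1 against WT gave 1 gene with no filter and 0 to 1 with 1 library left out. OX9 against WT gave 8 with the repeat-by-treatment block, 0 with its own groups alone, and 0 to 3 with 1 library left out. The difference of response gave 0 for both lines whichever library was left out, and 1 gene for OX9 with its own groups alone. Where a library is left out, the lone library of its group is assumed to vary like the other groups.

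Most list calls rest on the preset correlation. With an estimated correlation the called lists went from 12 to 1 for flg22 in WT, from 11 to 1 in asr3-1 and from 10 to 1 in OX9; fry called 5, 3 and 1. With the replicate block an estimated correlation left 1, 0 and 0 lists, and with the repeat-by-treatment block 8, 7 and 7, where fry called 11, 12 and 12; after quantile normalization it left 4, 1 and 1. For asr3-1 against WT without flg22, 2 lists became 0 with an estimated correlation, with fry and with the replicate block, 4 with either scaling and 6 with the repeat-by-treatment block. For OX9 against WT without flg22, 4 became 0 with an estimated correlation, 1 with fry, 1 with the replicate block and 7 with the repeat-by-treatment block. With flg22, asr3-1 against WT went from 7 to 0 with an estimated correlation and 0 with fry. OX9 against WT went from 6 to 0 and 1 with these, and to 11 with the repeat-by-treatment block; an estimated correlation left 1 list with the replicate block or after quantile normalization. The difference of response of OX9 went from 5 lists to 0 and 0, and to 9 with that block, of which an estimated correlation left 3; with the replicate block it left 1 of 6.

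Over the 40 genes raised in asr3-1, the medians for OX9 against WT (0.39 without flg22, -0.33 with it, -0.77 for the difference of response) did not pass with an estimated correlation. The last did pass with it after quantile normalization (adjusted p = 0.037) and trimmed mean scaling (0.046). Without scaling, the same correlation took away the calls over the 795 genes (0.14, -0.36 and -0.49) and, for asr3-1 against WT, over the 487 genes (0.17 with flg22 and 0.06 for the difference). The asr3-1 value without flg22, 0.12, passed with the repeat-by-treatment block, and so did 0.14 over genes raised in WT itself, but neither with an estimated correlation (adjusted p = 0.29 and 0.80). The asr3-1 difference of response did not pass over genes raised in WT itself (0.01) or with transcripts of at least 1000 bases (0.05).

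With 1 library left out, the medians over the 40 genes ran from 0.11 to 0.68 without flg22, from -0.80 to 0.05 with it and from -1.19 to -0.43 for the difference. Over the 795 genes they ran from 0.05 to 0.21, from -1.16 to 0.39 and from -1.30 to 0.26. Over the 487 genes in asr3-1 they ran from 0.10 to 0.14, from -0.79 to 1.13 and from -0.84 to 0.99. The direction turned without the treated WT library of repeat 2 (0.05 over 40 genes; 0.39 and 0.26 over 795) or the treated OX9 library of repeat 1 (0.35 and 0.18). In asr3-1 it turned without the treated WT library of repeat 1 (-0.72 and -0.81) or the treated asr3-1 library of repeat 2 (-0.79 and -0.84). Such a step sets repeat 1 of one genotype against repeat 2 of the other, and the median response of the 795 genes in WT was 1.72 and 3.18 in these.

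For ASR3 and the markers, 50 values changed direction with 1 library left out and 1 with a pseudocount of 0.1, none of which had passed before or passed then. ASR3 with flg22 in WT went from -0.07 to 0.21 without the untreated library of repeat 1, and in the difference of response of OX9, CYP81F2 went from -1.17 to 0.11 and WRKY33 from -1.11 to 0.02 without the treated WT library of repeat 2. Leaving out that library sets treated WT of repeat 1 against both repeats of OX9. Within repeats 1 and 2 the difference was -1.51 and -0.84 for CYP81F2 and -1.48 and -0.74 for WRKY33. The replicate block changed no other call than those given.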

Other observations

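Both observations below were made after the data were seen, and no test in this part was planned.

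A few genes differed from WT by at least 2-fold the same way in all 4 pairs of libraries matched by repeat and condition. In OX9 11 genes were higher in all 4 pairs and 0 lower, where any other of the 14 mixed patterns of direction held at most 2 genes. They are ASR3, the noncoding RNA AT2G01422, the purple acid phosphatase PAP22, the zinc finger gene NUB, the carboxypeptidase-like gene scpl33, SADHU3-2, AT1G43590, AT3G55290, AT3G57160, AT4G11310 and AT5G19810. PAP22 ran from 0.678 to 4.47 FPKM in the WT libraries and from 15.7 to 24.2 in OX9. In asr3-1 2 genes were higher (the small nuclear RNA U12, AT1G61275, and the pseudogene AT5G35935) and 3 lower, with at most 2 genes in any mixed pattern. The lower ones were AT5G24240, AT5G35940 and FHIT (AT5G58240), a gene of the fragile histidine triad family, which lay between 39.3 and 47.5 FPKM in WT and between 14.2 and 18.7 in asr3-1 (log2 -1.33, SE 0.16, averaged over both conditions). FHIT did not pass the test of that average (adjusted p = 0.48, 0.099 with the replicate block, 0.053 with the repeat-by-treatment block). Averaged over both conditions, 2 genes passed in OX9 (ASR3 and AT2G01422) and 0 in asr3-1 in limma (177 at an unadjusted p under 0.05). The replicate block added AT3G57160 in OX9, and the repeat-by-treatment block PAP22 besides; in asr3-1 that last model called AT1G78420, UBP20 and AT5G11330.

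Among small RNAs and other short transcripts, the 29 genes seen in repeat 1 alone include 15 small nucleolar RNAs and 12 protein coding genes, and their median transcript length was 120 bases.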
